A study of Beta vulgaris subsp. vulgaris with 30 samples.

How the data were processed

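RNA from sugar beet shoots was sequenced in 30 libraries, 6 in each of 5 groups taken from the sample titles and treatment labels. Per the submitters' processing notes, bcl2fastq, Trimmomatic, HISAT2, featureCounts and DESeq2 were used, with versions not given in the sources used here. Those notes name the Arabidopsis build TAIR10, whereas per the file headers the genes lie on chromosomes of the beet assembly EL10.2, with beet gene identifiers. The deposited table of counts holds whole read counts for 21587 genes, of which 2180 have no read in any library. The authors' second deposited table gives a signal per gene that equals the count divided by 1 size factor per library, with a relative spread of at most 1.2e-09 within a library, so it was used only for that check. All tests used the deposited counts. The length column equals the full span of the gene in every row. Whether reads were counted by strand is not given in the sources used here, and 582 genes overlap a neighbour, so their counts are uncertain.

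Of the rows of the deposited table, 12.65% (2730) stand out of the order of their identifiers. Identifier and chromosome column name the same chromosome in 21572 of the 21572 genes whose identifier names one, and both tables have the same row order. Genes were therefore sorted by position before any use of neighbours. No pair of libraries held identical counts.

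The files used here pair the identifiers with no gene names. Names came from a RefSeq table of EL10.2 genes, matched by position where each gene covered at least 0.5 of the other. This paired 15778 genes, or 73.09%, but only 15 have a symbol other than a locus number, and no product descriptions were used. The design, the other settings, the 28 gene lists and the rule for named genes were fixed before the data were examined. The lists found 0 genes, so the camera tests of gene lists were not run. By the rule, genes past the threshold with symbols could be named, and otherwise at most 2 identifiers that rose and 2 that fell per comparison, those with the largest fold among genes past the threshold with a mean of at least 5 CPM in the higher group. Genes named for the lowest p, for abundance, as members of a count of 5 or fewer, or with a symbol but not past the threshold were chosen after their values were seen.

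Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group numbered 14128 and held 99.92% of the reads. TMM factors were computed and a quasi-likelihood model with 5 group means and no covariate was fitted to all 30 libraries. The 6 comparisons were contrasts of these means, tested on 2 sides with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. The square root of the common dispersion was 0.593. Principal components used log2 CPM with a prior count of 2. The other settings planned were relative log expression scaling, no low-count filter, the replicate number as a block, fits of the compared groups only, and the Wald test of DESeq2 1.42.0. Leaving out each compared library was added after the data were seen. Exact permutation tests, and sampled ones with 100000 draws for correlations and scores, 2000 for matched shares of genes and 1000 for neighbours, used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

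Total counts ran from 3379082 to 17868082 with a median of 9268172. No library fell below 3089390, the limit set relative to the median for a planned fit without shallow libraries, so that fit was not run. The labels name no molecular identifiers, so counts are taken as reads and not as molecules. The tests were tested on simulated counts drawn with the real means, library totals and dispersions, in which 200 genes were changed between ethanol and water. Of 83 calls, 4 were of genes not changed.

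The gene models of the count table are not alike across the genome, which limits any comparison of levels between genes, including which genes are most abundant. On chromosomes 1, 3, 4, 5, 6 and 8 and from 35 Mb on chromosome 7, RefSeq models reached a median of 256 bp further at the 3′ end, and on the rest they ended a median of 98 bp before the table's models. Reads at transcript ends outside a model are not in the table.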

Results

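Messenger RNA was counted in shoots of sugar beet seedlings that stood in water or in dilute ethanol before a freezing treatment. The 30 libraries fall into 5 groups of 6, which were sampled before pretreatment, after water, after ethanol, after water and then freezing, and after ethanol and then freezing. The series description gives 7-day-old seedlings, pots standing in 80 mM ethanol for 3 days, and a night at -2.1 to -3.5 °C, whereas the protocols attached to the individual samples describe Arabidopsis plants aged 14 days, 20 mM ethanol for 6 days and -4.0 °C. The group names carry 3 days of pretreatment and 2 h beside the freezing temperature, and do not say from when the 2 h were counted. Of the 21587 genes counted, 21572 have identifiers that name a chromosome of the sugar beet assembly EL10.2. The beet description is therefore followed here. Libraries were made with Lasy-Seq, a multiplexed RNA-seq method that primes on the poly(A) tail, from 200 ng of total RNA each. Total counts ran from 6658906 to 14171223 before pretreatment, 6318167 to 14296414 after water, 3379082 to 15804988 after ethanol, 6632495 to 15893565 after water and freezing, and 7958897 to 17868082 after ethanol and freezing. Between 11985 and 15510 genes had at least 1 read in a library. Levels are in CPM, counts scaled to a common library total with TMM factors, given as mean ± SD, and changes are log2 fold changes with their standard errors. The labels name no separate cultures, so p-values measure the spread between these samples.

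The 5 most abundant genes of a library held 11.08 to 18.88% of its counts. Of the 5 with the highest mean share, 4 lie on chromosome 2 between 52726504 and 52778991, and Bevul.7G217400 (59462404 to 59463207) lies on chromosome 7. Component 1, with 11.6% of the variance, separated all 12 frozen libraries, at 13.82 to 65.98, from the 18 unfrozen ones, at -66.13 to -16.3. The libraries taken before pretreatment lay at -27.86 or below on component 2, and ethanol replicate 4, the library with the lowest total count, lay alone at 154.43. On component 4, with 4.46% of the variance, water replicate 3 lay at 121.27 and the other water libraries at -16.66 to 4.1.

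**Figure D1:**
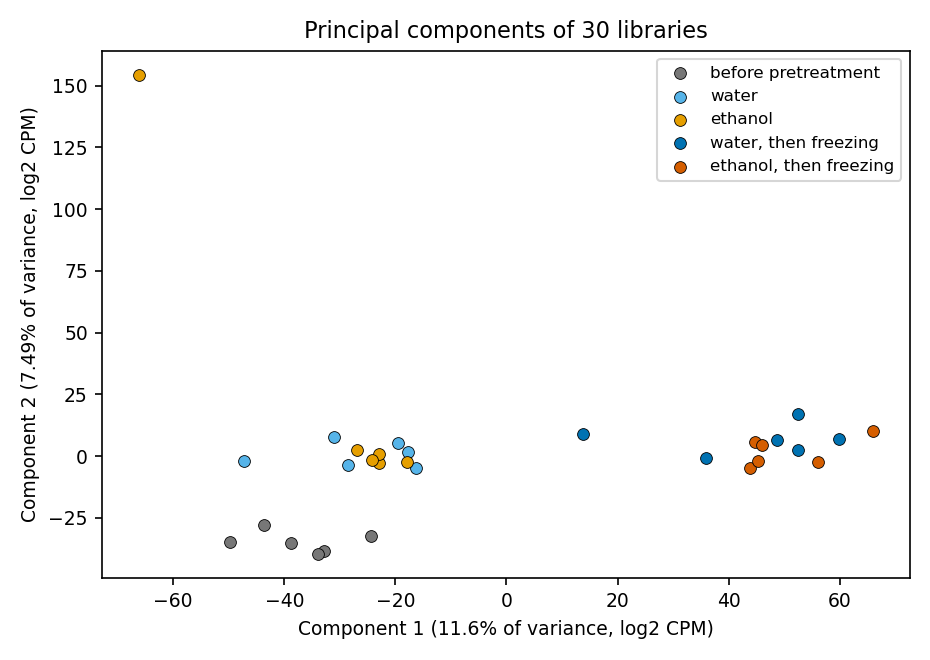
Each point is 1 of the 30 libraries, placed by components 1 and 2 of the log2 CPM of 14128 genes and coloured by group. The 12 frozen libraries lie at 13.82 or above on component 1, and ethanol replicate 4 stands apart at 154.43 on component 2.

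Freezing after water raised 709 genes and lowered 861 of the 14128 genes tested. Bevul.9G090900 (chromosome 9, 30628972 to 30630792) rose from 154.5 ± 45.2 to 1255 ± 287 CPM (n = 6 each), a log2 change of 3.02 ± 0.25 (SE), and stood at 45.3 ± 16.1 CPM before pretreatment. Bevul.7G152200 (chromosome 7, 49612746 to 49613549) fell from 79.2 ± 15.4 to 14.6 ± 3.42 CPM, a log2 change of -2.43 ± 0.19. Both were singled out afterwards as the genes with the lowest adjusted p in each direction, 1.68e-10 and 4.75e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and in both the 6 frozen libraries lay outside the range of the 6 unfrozen ones. Among called genes with a mean of at least 5 CPM in the higher group, those that rose most by fold were Bevul.2G074100 (chromosome 2, 15773988 to 15780625), from 0.587 ± 1.1 to 14.9 ± 6.92 CPM, and Bevul.8G194200 (chromosome 8, 58888307 to 58891526), from 0.257 ± 0.278 to 5.66 ± 8.21 CPM. Under the same limit, those that fell most were Bevul.5G243900 (chromosome 5, 65696005 to 65696294), from 398 ± 425 to 9.39 ± 1.97 CPM, and Bevul.1G169300 (chromosome 1, 58152224 to 58154806), from 19.97 ± 21.2 to 0.448 ± 0.786 CPM. Both varied widely between the water libraries, from 10 to 849 CPM for Bevul.5G243900 and from 0.171 to 44.1 CPM for Bevul.1G169300.

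Of the abundant genes, Bevul.2G213400 (chromosome 2, 52770291 to 52771961) fell from 4.53 ± 0.436% of the counts after water to 1.88 ± 0.74% after freezing, with a log2 change of -1.43 ± 0.19 and an adjusted p of 1.15e-06 by edgeR. Its neighbours Bevul.2G213100, Bevul.2G213200 and Bevul.2G213500 fell by 0.85, 0.40 and 0.50 on the log2 scale. Bevul.7G217400 had a log2 change of -0.02 ± 0.10 (adjusted p = 0.958). These genes were singled out after their values were seen. At least 2-fold changes were found in 363 of the genes that rose and 297 of those that fell. The call of Bevul.8G194200 was lost without water replicates 2, 5 or 6 or frozen water replicate 3, where its adjusted p was 0.0522, 0.052, 0.0555 and 0.124. Its range was 0.0124 to 0.124 over the alternatives that gave it an adjusted p, which leaves out a planned setting. The labels give no sampling hour, so freezing and time of day cannot be told apart in this comparison or in that after ethanol.

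Only 15 of the genes carry a symbol in the RefSeq annotation, and all 15 were tested. After water, freezing raised BTC1 (Bevul.2G112000, chromosome 2, 34011577 to 34020955), a pseudo-response regulator that controls bolting time in beet, from 29.8 ± 4.98 to 44.2 ± 11.3 CPM, a log2 change of 0.57 ± 0.17 with an adjusted p of 0.0232 by edgeR. The other 14 did not pass the threshold. Among them, agpS1, a small subunit of ADP-glucose pyrophosphorylase, which supplies starch synthesis, stood at 13.6 ± 2.71 and 22.4 ± 8.29 CPM, with an adjusted p of 0.0694. The nitrate reductase gene nr1 stood at 182.2 ± 14.6 and 134.4 ± 27.1 CPM, with an adjusted p of 0.0746. The sucrose transporter sut1, the sucrose synthase SBSS1 and the clock gene PRR7 had log2 changes of 0.27 ± 0.26, 0.25 ± 0.25 and 0.41 ± 0.29. The BTC1 call was lost without water replicates 2 or 5 or frozen water replicate 2, with adjusted p values of 0.0646, 0.0622 and 0.119, and in a fit of the compared groups only, at 0.0668, within a range of 0.0105 to 0.119 over all alternatives. DESeq2 called agpS1 and nr1, at 0.0474 and 0.0312, as did fits without frozen water replicates 1 and 4 for agpS1 (0.0215 and 0.0438; range 0.0215 to 0.213) and, for nr1, a fit of the compared groups only (0.0399) and those without frozen water replicates 5 and 6 (0.0499 and 0.0433; range 0.0312 to 0.193).

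Freezing after ethanol raised 817 genes and lowered 923. Bevul.9G090900 rose from 169.6 ± 42.2 to 1165 ± 481 CPM (n = 6 each; log2 change 2.78 ± 0.25) and Bevul.7G152200 fell from 73.5 ± 12 to 17.2 ± 1.84 CPM (log2 change -2.09 ± 0.18), and these 2 again had the lowest adjusted p in their direction, 1.37e-09 in each case by edgeR. Among called genes with a mean of at least 5 CPM in the higher group, Bevul.6G187100 (chromosome 6, 63156660 to 63157238) rose most by fold, from 0.827 ± 1.28 to 31.1 ± 21.6 CPM, followed by Bevul.2G074100, from 0.854 ± 0.786 to 17.8 ± 10.4 CPM. Under the same limit the largest falls were those of Bevul.3G125000 (chromosome 3, 20212491 to 20212799), from 6.37 ± 1.76 to 0.235 ± 0.356 CPM, and Bevul.7G090100 (chromosome 7, 25631460 to 25631789), from 18.03 ± 8.29 to 0.984 ± 0.744 CPM. The abundant gene Bevul.2G213400 fell from 4.56 ± 0.285% to 1.7 ± 0.503% of the counts.

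Among the 15 genes with a symbol, nr1 (Bevul.3G009200, chromosome 3, 1147077 to 1150208) fell from 176.9 ± 21 to 126.2 ± 29.5 CPM after ethanol and freezing, a log2 change of -0.49 ± 0.16 with an adjusted p of 0.0385 by edgeR. BV-16/1 (Bevul.1G174400, chromosome 1, 58834395 to 58838186) rose from 88.1 ± 15.9 to 117.3 ± 13.1 CPM, a log2 change of 0.41 ± 0.13 with an adjusted p of 0.0301. BTC1 stood at 37.9 ± 5.88 and 44.8 ± 9.38 CPM, with an adjusted p of 0.447. Its freezing response after ethanol differed from that after water by -0.32 ± 0.24 on the log2 scale (adjusted p = 1), so no difference between pretreatments was shown. The nr1 call was lost without ethanol replicates 1, 2, 3, 5 and 6 (adjusted p 0.0592, 0.0525, 0.067, 0.069 and 0.0866) or frozen ethanol replicates 1, 3 and 4 (0.0596, 0.105 and 0.12), and ranged from 0.0135 to 0.12. The BV-16/1 call was lost without ethanol replicates 1 to 4 (0.0815, 0.0683, 0.0827 and 0.0747), frozen ethanol replicates 2, 4 and 5 (0.0645, 0.064 and 0.0712) or the other groups (0.0728), and ranged from 0.00966 to 0.0827. Without a low-count filter both adjusted p values were 0.0516.

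**Figure D2:**
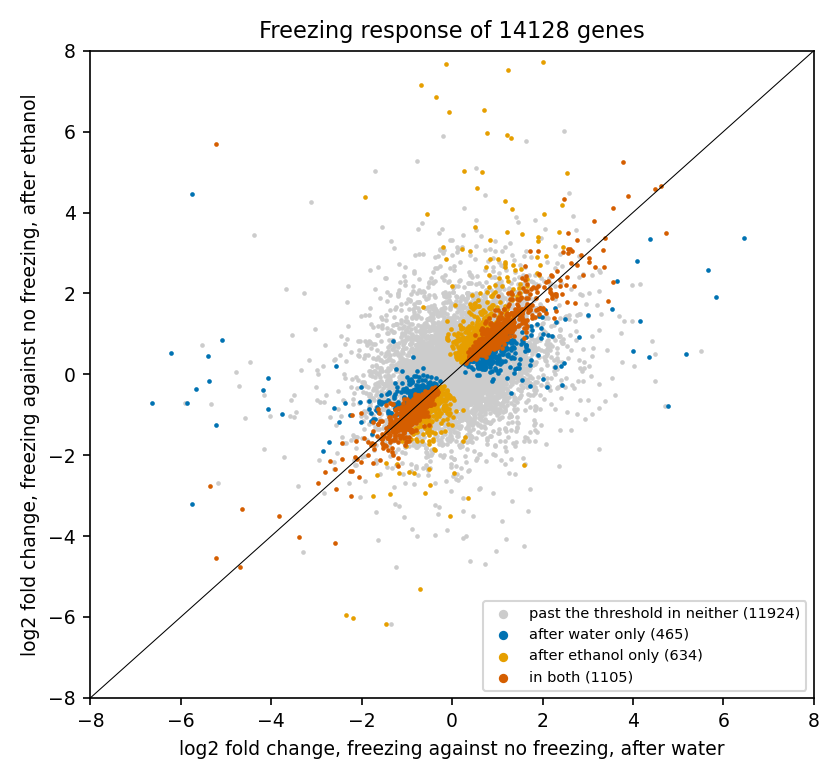
Each point is 1 of 14128 genes, with its log2 fold change from freezing after water on the x axis and after ethanol on the y axis, coloured by whether edgeR's adjusted p passed 0.05 in neither, either or both; the line marks equal change. Most of the 1105 genes past the threshold in both lie near the line.

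The freezing responses after water and after ethanol come from separate libraries and shared 1105 genes. Of these, 458 rose in both, where independent lists would share 41, and 646 fell in both, where 56.3 would be shared. Both lists came from the same fit, and genes that are easier to call may enter both, which these expectations leave out. The remaining shared gene, Bevul.4G107700 on chromosome 4, fell after water and rose after ethanol, but held 1.06 ± 0.94 CPM after water, 0.0161 ± 0.0395 after water and freezing, 0 after ethanol and 0.626 ± 0.767 after ethanol and freezing. Of the 2205 genes called after either pretreatment, 97.6% had log2 changes of the same sign after both, whether or not both passed the test. Across genes, which are not independent replicates, Pearson's r of the 2 log2 changes was 0.448 and Spearman's rho 0.51. Over the 5406 genes with a mean of at least 10 CPM, r was 0.841. Without the low-count filter r was 0.124. A difference in time of day could be common to both responses, so their agreement does not tell freezing from time of day.

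Ethanol against water before freezing asked what the pretreatment changed on its own, and 1 gene passed the test. Bevul.5G150600 (chromosome 5, 44469089 to 44469890, minus strand) held 64.05 ± 13 CPM after water and 22.3 ± 4.58 CPM after ethanol (n = 6 each), a log2 change of -1.52 ± 0.27 with an adjusted p of 0.0383 by edgeR, and the 6 ethanol libraries lay below all 6 water libraries. It held 11 ± 2.26 CPM before pretreatment, 40 ± 25.4 CPM after water and freezing and 21.98 ± 7.94 CPM after ethanol and freezing. No gene was higher after ethanol. At an unadjusted p under 0.05 there were 558 genes where chance gives 706. Without the low-count filter there were 1816 of 19407, more than chance gives, so this count depended on the filter. DESeq2 called 4 genes higher and 5 lower. None of the 15 genes with a symbol passed. Counts were simulated for this comparison over the same 14128 genes. The test recovered 26% of 50 genes changed 2-fold and 60% of 50 changed 4-fold. Of those with a mean of at least 10 CPM, it recovered 13 of 18 and 21 of 21. The simulation gave 83 calls in all, against 1 in the real comparison. Benjamini-Hochberg adjustment is more lenient where more genes change, so these shares may overstate what the real test could recover. The call of Bevul.5G150600 was lost in 10 of the 12 fits that left out 1 library, without water replicates 1, 2, 3, 5 and 6 (adjusted p 0.0572, 0.0732, 0.114, 0.115 and 0.112) or ethanol replicates 1, 2, 3, 5 and 6 (0.233, 0.117, 0.0712, 0.0991 and 0.106), and its adjusted p ranged from 0.00074 to 0.233 over all alternatives.

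Ethanol against water in frozen shoots called 3 genes higher and 12 lower. The 3 higher genes were the neighbours Bevul.5G243900 and Bevul.5G244000 (chromosome 5, 65699448 to 65700019) and Bevul.5G006000 (chromosome 5, 838818 to 839681). Bevul.5G244000 held 527.3 ± 281 CPM after ethanol and 4.98 ± 2.73 CPM after water (n = 6 each; log2 change 6.73 ± 1.23; adjusted p = 0.0103 by edgeR), and Bevul.5G243900 held 996.6 ± 552 and 9.39 ± 1.97 CPM. Both were high in 5 of the 6 ethanol libraries and in none of the 6 water libraries. Bevul.5G006000 held 9.36 ± 2.71 and 2.48 ± 1.76 CPM. Of the lower genes, Bevul.1G104100 (chromosome 1, 47578955 to 47579917) held 55.6 ± 19.5 CPM after ethanol and 198.3 ± 91.3 after water, a log2 change of -1.83 ± 0.31. Bevul.9G040600 (chromosome 9, 8298156 to 8302969) held 12.4 ± 4.2 and 42.1 ± 12 CPM, a log2 change of -1.75 ± 0.33. Bevul.3G143500 (chromosome 3, 30408455 to 30412085), singled out for the lowest adjusted p, 0.000156, held 49.8 ± 12.9 and 134.5 ± 35.3 CPM, with the ranges of the 2 groups apart.

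None of the 15 genes with a symbol passed between the frozen groups. The counts were less firm than those for freezing. The lower genes numbered 4 when only the compared groups were fitted and 25 by DESeq2, and the higher ones 11 by DESeq2. Leaving out frozen water replicate 1 gave 21 lower genes and frozen water replicate 6 gave 4, and frozen ethanol replicates 1, 3 and 4 gave 7, 7 and 6. Frozen water replicate 6 lay lowest of the frozen libraries on component 1, at 13.82, with the others at 35.9 or above. The higher genes numbered 6 without frozen water replicate 3 and 1 without frozen water replicate 6. The call of Bevul.5G006000 was lost without frozen water replicates 2, 3, 4 and 6 (adjusted p 0.103, 0.0852, 0.12 and 0.124) or frozen ethanol replicates 2 to 6 (0.0677, 0.0623, 0.108, 0.0712 and 0.102), and was 0.268 in a fit of the compared groups only, where that of Bevul.1G104100 was 0.0697. That of Bevul.9G040600 was lost without frozen ethanol replicate 4 or frozen water replicate 6, at 0.0589 and 0.0656, and that of Bevul.5G243900 without frozen water replicate 6, at 0.0656.

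The difference between the freezing responses, tested gene by gene, called no gene higher and none lower by edgeR or by DESeq2. At an unadjusted p under 0.05 there were 406 genes where chance gives 706, and the lowest adjusted p was 0.925. Without the low-count filter 1213 of 19407 genes lay under that unadjusted p, more than chance gives, so this count depended on the filter. Bevul.9G090900 had a difference of -0.24 ± 0.32 and Bevul.7G152200 of 0.34 ± 0.25 on the log2 scale. The median SE of the difference was 0.614, which limits what could be seen for most genes. A freezing score, defined after the calls were seen as 0.5 times the mean log2 CPM of the 458 genes that rose in both minus that of the 646 that fell, rose by 1.09 after water and by 1.13 after ethanol. The difference of 0.0446 had a bootstrap 95% interval of -0.133 to 0.242 and a permutation p of 0.689 (two-sided, pretreatment labels permuted within frozen and unfrozen libraries, n = 6 per group). Because its genes were chosen in these libraries, the score does not test for freezing. It describes the size of the response only for genes called after both pretreatments. Genes called after either pretreatment but not both were left out, which favours similar rises. Neither the interval nor the permutation p accounts for that choice, so the score does not decide whether ethanol changed the size of the response.

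**Figure D3:**
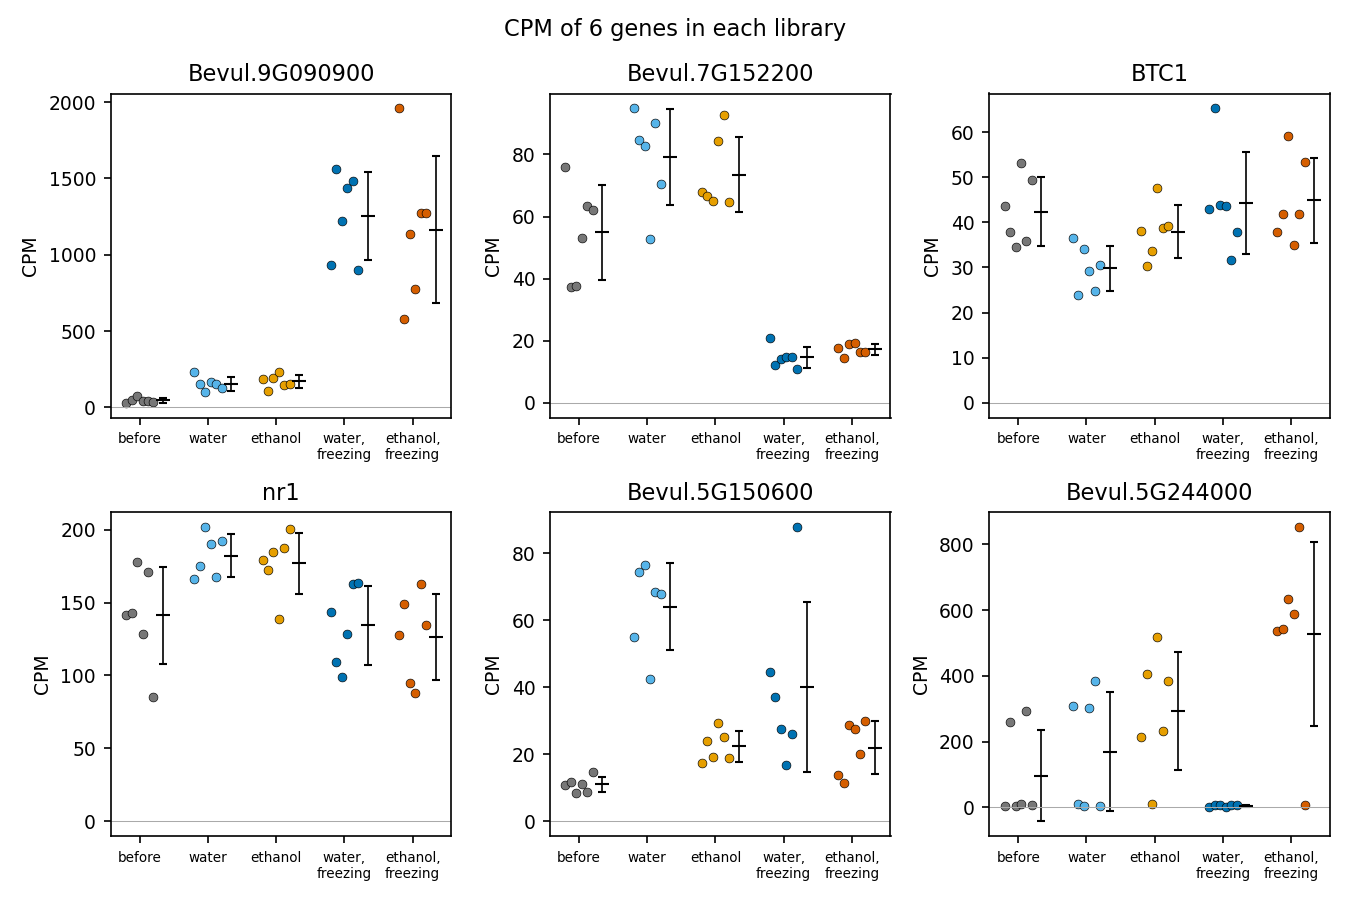
CPM of 6 genes in each library, with 1 panel per gene, points for the 6 libraries of a group, and a bar beside them for the mean and SD; each CPM axis is linear. Bevul.9G090900 rose and Bevul.7G152200 fell with freezing after both pretreatments, Bevul.5G150600 was lower after ethanol than after water, and Bevul.5G244000 was either high or near 0 in each library.

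Water pretreatment against the state before it gave the change over the pretreatment days without ethanol, with 231 genes higher and 206 lower. Bevul.4G241200 (chromosome 4, 64805600 to 64806209) rose from 172.0 ± 19.3 to 555 ± 102.5 CPM (n = 6 each; log2 change 1.69 ± 0.16) and Bevul.7G027700 (chromosome 7, 4269514 to 4270743) fell from 149.4 ± 23.5 to 42.8 ± 7.96 CPM (log2 change -1.80 ± 0.19), and these 2, singled out for the lowest adjusted p, had values of 1.9e-08 and 9.39e-08 by edgeR. Of the genes with the largest folds among those with a mean of at least 5 CPM in the higher group, Bevul.9G190500 (chromosome 9, 50398965 to 50400188) rose from 0.535 ± 0.558 to 5.4 ± 4.08 CPM and Bevul.6G033300 (chromosome 6, 5335451 to 5337201) from 0.59 ± 0.57 to 5.34 ± 2.96 CPM. Bevul.7G088300 (chromosome 7, 24845320 to 24846141) fell from 17.8 ± 19.6 to 0.112 ± 0.145 CPM and Bevul.6G233600 (chromosome 6, 70219982 to 70224473) from 6.79 ± 2.9 to 0.069 ± 0.169 CPM, with reads in 1 of the 6 water libraries. None of the 15 genes with a symbol passed. DESeq2 called 351 genes higher. The call of Bevul.7G088300 was lost without replicates 3, 5 and 6 before pretreatment (adjusted p 0.0541, 0.0614 and 0.061) or any 1 water replicate (0.0805, 0.0776, 0.0623, 0.0776, 0.0619 and 0.0744), and ranged from 0.0171 to 0.0805. That of Bevul.9G190500 was lost without replicates 1 to 4 before pretreatment (0.0771, 0.0708, 0.0774 and 0.0737) or water replicates 2 and 4 (0.0966 and 0.0655), and ranged from 0.00263 to 0.0966.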

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

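The tests of gene models, of single reads and of the pair on chromosome 5 were chosen after the pattern was seen, and those of matched shares and of PCR copies were not; components 3 and 4 were searched only after their values were seen. Among 100 sets of 6 libraries searched for a library far from its fellows, 15 had one, where chance gives about 1 in 20. The value in brackets is the gap to the nearest library as a share of the range.

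Ethanol replicate 4 stood apart in genes detected (11985, next 13789; 0.639), on component 1 (-66.13, next -26.92; 0.813), on component 2 (154.43, next 2.42; 0.966) and on component 3 (49.56, next -21.4; 0.788), and has the lowest total count of the 30 libraries. Frozen ethanol replicate 5 had the highest total count (17868082, next 11025358; 0.691). Leaving out either moved no count of genes changed by freezing after ethanol over 1.5 times. Without ethanol replicate 4, ethanol against water before freezing gave 0 genes higher and 2 lower, against 0 and 1 with all libraries. Water replicate 3 stood apart on component 4 (121.27, next 4.1; 0.849), as did replicate 2 before pretreatment (26.87, next -6.21; 0.628). Without water replicate 3, freezing after water changed 629 genes upward and 790 downward, the water pretreatment 214 and 189, and ethanol against water before freezing 0 and 0, where the adjusted p of Bevul.5G150600 was 0.114 and, over the water pretreatment, that of Bevul.7G088300 was 0.0623 by edgeR.

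Single libraries stood apart at 8 named genes. Bevul.1G169300 held 2.03 CPM in frozen water replicate 3, next 0.302 (0.851). Bevul.2G074100 held 2.77 CPM in water replicate 5, next 0.621 (0.776). BTC1 held 65.3 CPM in frozen water replicate 2, next 43.9 (0.635), and its call was lost without that library, at an adjusted p of 0.119 by edgeR. Bevul.3G125000 held 0.917 CPM in frozen ethanol replicate 1, next 0.278 (0.697). Bevul.6G187100 held 3.41 CPM in ethanol replicate 3, next 0.642 (0.812). Bevul.3G143500 held 24.9 CPM in frozen ethanol replicate 1, next 48.1 (0.635). Bevul.6G233600 held 0.414 CPM in water replicate 1 and 0 in the other 5 (1 of the range). Bevul.5G244000 held 6.41 CPM in frozen ethanol replicate 6, next 538.3 (0.628).

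Bevul.5G243900 and Bevul.5G244000 were on or off together in 30 of 30 libraries, with no value of Bevul.5G244000 between 11 and 223 CPM, here scaled by the library total alone and not by TMM factors. They were on in 2 of 6 libraries before pretreatment, 3 after water, 5 after ethanol, 0 after water and freezing and 5 after ethanol and freezing, and since the pair was singled out by its call between the frozen groups, these counts are no separate evidence for ethanol. Ethanol as the whole cause is argued against by the 5 libraries without ethanol that were on, and reads shared through overlap by the 3154 bases between the genes. Seedlings of different genotype cannot be told apart from other sources, since the gap of 4.33 in log2 values on that scale needs genotypes to interpret. A part played by ethanol also stays open.

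Genes on chromosomes 2 and 9 and the first 35 Mb of chromosome 7, whose models reach further at the transcript ends, held a median of 1340 reads against 514 elsewhere. Within chromosome 7 the ratio of the medians of the 2 parts was 1.69, above the 0.614 to 1.28 found on 6 chromosomes with uniform models, so models that miss transcript ends may lose reads, although 1.69 does not bear on whether chromosomes 2 and 9 also carry more active genes, which cannot be told apart from this. Freezing after water called 14.5% of genes with long models and 9.8% of the others. Matched on deciles of mean CPM, the difference was -1.91 percentage points (permutation p = 0.0005, the smallest that 2000 permutations can give), where a p under 0.05 had been set beforehand as evidence against read depth as the source. That criterion left out the sign: the excess was gone, as depth would have it, but depth alone gives no reversal, which was also found after ethanol (-1.56 points, permutation p = 0.004) and not for the water pretreatment (4.5 against 2.5% called, matched difference 0.16 points, permutation p = 0.6), so depth stays open, and no biological explanation was tested.

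Genes detected in 1 library of 30, 1152 in all, held a median of 6 reads there. Single reads made up 17.3% of these detections, a share that the median already holds low, so it decides nothing about stray reads from other libraries. PCR copies of single molecules were predicted to grow with the total count, but the median count at genes found in at most 3 libraries gave Pearson's r of 0.178 (permutation p = 0.347) and Spearman's rho of 0.241 (permutation p = 0.199) over 30 libraries, and r of 0.168 without the 2 farthest totals. That prediction was wrong in its premise, since Lasy-Seq pools samples before amplification and copies need not follow depth. Stray reads and PCR copies therefore stay open, and no biological explanation was tested.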

How the results depend on the processing

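Leaving out each library was chosen after the data were seen; the other settings were planned. Counts of genes changed by freezing stayed within 1.5 times, at 625 to 840 higher and 803 to 1030 lower after water and 746 to 917 and 845 to 1109 after ethanol over the planned settings, and 573 to 728, 724 to 935, 675 to 762 and 798 to 981 without 1 library. Under DESeq2, ethanol against water before freezing gave 4 higher and 5 lower against 0 and 1, the frozen groups 11 and 25 against 3 and 12, and the water pretreatment 351 higher against 231. With only the compared groups fitted, ethanol against water gave 2 higher and 3 lower, and the frozen groups 4 lower. The cause was not tested. Leaving out 1 library gave 0 to 1 higher and 0 to 2 lower for ethanol against water, and 1 to 6 higher and 4 to 21 lower between the frozen groups. The difference of freezing responses stayed at 0 genes in every fit. The correlation of the freezing responses, 0.448, was 0.124 without the low-count filter, which adds genes with few reads, and 0.419 with the replicate block. Same-numbered libraries did not deviate together (correlations -0.038 to 0.054, and 8 of 30 libraries closest to their own number), so no pairing by number was seen. How the samples were numbered cannot be told from this. The block moved no count of calls over 1.5 times. Under it the adjusted p by edgeR of Bevul.1G169300 after water and freezing was 0.061 and that of Bevul.5G006000 between the frozen groups 0.0608. Of 472 values of 28 called gene results under other settings, 405 stayed past the threshold, 67 did not and 0 reversed. Of 1644 values of uncalled ones, 7 passed. A setting that filtered out a gene or gave it no adjusted p holds no value in these counts. Among the called results this was so for Bevul.1G169300, Bevul.6G233600, Bevul.7G088300 and Bevul.8G194200. The planned gene list tests were not run because the lists found no genes, and the fit without shallow libraries because none qualified. At the depth and spread of these libraries, 26% of simulated 2-fold changes between ethanol and water were recovered over 14128 genes. The simulation gave 83 calls in all, and with fewer changed genes that share may be lower, because the adjustment depends on their number. Whether depth or spread limited the recovery was not tested.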

Other observations

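The tests of neighbours, scores and overlaps were chosen after the results were seen; the splits of the libraries were planned.

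Genes that changed in the same direction with freezing lay next to one another in more pairs than most permutations gave. After water, 142 adjacent pairs of tested genes changed in the same direction, against a mean of 90.7 in 1000 permutations of calls within chromosomes, none of which reached it, and after ethanol 136 against 111.5, reached by 7 permutations. Runs of at least 3 such neighbours numbered 12 after water against a mean of 5, reached by 5 of the 1000 permutations, but 11 after ethanol against 6.9, reached by 77, so the number of runs after ethanol was not beyond chance. On chromosome 4, 7 neighbours from 61599549 to 61632990 all rose after water, by 0.48 to 2.38 on the log2 scale. On chromosome 3, 3 neighbours from 20212491 to 20242116 fell, with log2 changes of -5.76 to -4.69. After ethanol, 5 neighbours on chromosome 2 from 45703209 to 45900670 rose, by 1.04 to 2.64, some of them overlapping, and 4 on chromosome 9 from 41689136 to 41696047 had log2 changes of -1.34 to -0.96. Over the water pretreatment 24 adjacent pairs changed together against a mean of 7.3 and a highest of 18, among them 5 neighbours on chromosome 7 from 58734412 to 58784663, higher by 0.74 to 1.45, and 3 on chromosome 1 from 41493441 to 41549352, at -3.64 to -2.66. The 3 neighbours on chromosome 5 from 1764976 to 1778550 rose over the water pretreatment, by 1.25 to 1.41, and fell with freezing after water, at -0.61 to -0.45. Both comparisons use the same water libraries, so high values in those libraries alone would also give a rise and then a fall.

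Of the genes called after water and freezing, 84.5% stand in rows of the deposited table that are out of identifier order, against 11% of those not called. The share was 68.7% against 12.2% after ethanol and freezing, and 98.4% against 16.6% for the water pretreatment. For ethanol against water it was 100% both before freezing (1 gene) and in frozen shoots (15 genes), against 19.2 and 19.1%. Rows that carried wrong identifiers would scatter responding genes over the genome. Among those rows alone, adjacent pairs that changed together after water numbered 1.47 times the mean of 1000 permutations, whose highest was 1.41 times. This argues against wrong identifiers in all of those rows, but does not exclude them in some. After ethanol there were 82 such pairs, reached by 4 permutations, so the criterion of more pairs than in every permutation was not met there. No such test was made for the genes called between ethanol and water.

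Of the 12 genes lower in frozen shoots after ethanol than after water, 7 had risen over the water pretreatment, where independent lists would share 0.196, and these comparisons share no library (Fisher's exact p = 2.11e-10, two-sided, across genes). Both lists nevertheless came from the same fit of all libraries, with shared estimates of spread, and genes are not independent replicates. Genes that are easier to call may enter both lists, which the expectation of 0.196 leaves out. The Fisher p may therefore overstate the evidence for the overlap. A hypothesis is that ethanol may hold back part of the change over the pretreatment days. A score of the 231 genes that rose minus the 206 that fell over the water pretreatment, set to 0 before it, was 2.12 ± 0.145 after ethanol and freezing and 2.33 ± 0.167 after water and freezing (SD, n = 6 each), a difference of -0.205 with an exact permutation p of 0.0433 (two-sided, 924 splits). Without the lower genes called between the frozen groups the difference was -0.168 with an exact permutation p of 0.0909, so the test does not decide and the hypothesis stays open. In the unfrozen groups the score was 2.26 after ethanol and 2.62 after water, but the water libraries chose its genes. The 12 genes lower between the frozen groups were not chosen by unfrozen libraries. All 12 had log2 changes below 0 for ethanol against water in the unfrozen groups, a count that was not tested.

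A hypothesis that ethanol moves freezing genes before any freezing was not decided. With freezing genes chosen from 3 water libraries and tested against the 3 others, the score of ethanol minus held-out water was 0.0267 (exact permutation p = 0.5) and -0.00947 (p = 0.738; exact, n = 6 against 3, 84 splits each). A change by ethanol in the overall size of the freezing response was not decided either, with a difference of 0.0446 and a bootstrap 95% interval of -0.133 to 0.242. That score holds only genes called after both pretreatments, a choice that favours a small difference.

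Chance splits of the same libraries were set against each count, with 100 splits drawn per comparison and only the compared groups in the fit. The real split gave 1504 genes for freezing after water (highest other 7.18% of it), 1757 after ethanol (highest other 5), 368 for the water pretreatment (2), 5 for ethanol against water (2) and 7 between the frozen groups (4). In each of these only 1 of the 100 splits, the real one, gave as many, so chance can be excluded for freezing after either pretreatment and for the water pretreatment. For the 2 comparisons of ethanol with water the margins are small, so the splits alone are not taken to exclude chance there. In the fits of all libraries 558 and 499 genes lay at an unadjusted p under 0.05 by edgeR, below the 706 that chance gives. Without the low-count filter 1816 and 1687 of 19407 genes did, more than chance gives. These counts depend on the filter and decide nothing about chance. For the difference of the freezing responses the real count was 0 (highest other 1), which all 100 splits had to reach, so the splits say nothing about chance there.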
